A study of Rattus norvegicus with 6 samples.

How the data were processed

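Gene expression was measured in pineal glands of Sprague-Dawley rats with a single-channel Affymetrix rat array, on which each probe set is a group of short oligonucleotides designed against 1 transcript or expressed sequence. Per the labels' protocols, rats were kept on 14 h of light and 10 h of darkness, glands were taken at Zeitgeber time 7 (mid-day) and Zeitgeber time 19 (mid-night), counted in hours, RNA was extracted with Trizol and treated with DNase, and biotin-labelled cRNA was made from 10 µg of total RNA. Per the design text of the series, each of the 3 samples at a time point was a pool of glands. The number of glands per pool is not given in the sources used here. The p-values therefore measure the spread between pooled samples, and nothing in the labels says how far that spread is biological.

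The values deposited by the authors are probe set intensities on a linear scale, made with MAS5, the Affymetrix algorithm that turns the probes of a set into 1 signal, per the submitters' processing notes. The scaling target was read from the values: the mean signal after removal of 2% of the probe sets at each end was 99.99 on each of the 6 arrays, so each array had been multiplied by its own factor. This linear scaling equalizes the mean of the bright and middle probe sets and leaves the low end free to differ. The deposited table held 8799 rows, of which 59 were control probe sets. All 6 value columns matched samples by their labels, and 0 columns belonged to other samples. Detection calls, background and raw probe intensities were not used here, so a low signal could not be separated from background and no interval for a single array can be given. The number of arrays, 3 per group, limits the precision.

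Gene names came from the array's platform annotation as supplied. Of the 8740 probe sets other than controls, 7006 had 1 gene symbol, 308 had several and 1426 had none listed. The gene numbers of 6985 of the single-symbol probe sets were found in a reference table of assembly GRCr8, which was used for names only and updated 0 symbols. The probe sets with several symbols or none were tested and counted but not named, and probe sequences were not aligned here. No genome coordinates are given because no genome sequence was used.

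Signals were transformed to log2(signal + 16) without further scaling between arrays. Fold changes are on this scale, which understates the change of dim genes. Control probe sets were left out, and probe sets were kept when they lay above the 40th percentile of their array on at least 3 of the 6 arrays, which left 5409. The comparison of mid-night minus mid-day was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 4 residual and 5.16 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all kept probe sets, and a probe set was called at an adjusted p under 0.05. A gene was represented by its kept probe set with the highest mean over the 6 arrays, which gave 3246 genes. For genes below the 40th percentile on all arrays of a group and above it on all of the other, the fold change is given as a lower bound, computed against the higher of that percentile and the gene's own signal on each dim array. That percentile is a chosen floor, not a detection limit.

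Gene lists for 17 functions and 10 cell types were fixed before the data were examined, as were the comparison, the filter, the rule for named genes and all but the last 3 of the alternatives below. Each list with at least 4 measured genes was tested against all other genes with limma's camera, two-sided, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists tested. Camera with a correlation estimated per list and fry, which tests whether the genes of a list move on balance in a common direction, were run beside it. With an estimated correlation camera uses the 4 residual degrees of freedom, far fewer than with a preset one. Its p-values are larger for that reason too. The genes named are the 12 with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap, a fixed set of pineal genes, and from each list up to 4 called members with the largest change and up to 2 uncalled members with the highest signal. Genes named outside this rule are marked as chosen after their values were seen. Of the fixed set, Per1, Crx and Otx2 had no probe set carrying that name alone and were not analysed here.

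The procedure was tested on simulated arrays built for this comparison, with 10 draws of 5409 probe sets, of which 200 were changed in each draw. Changes of 0.5, 1 and 2 on the log2 scale were called in 3.13%, 49.6% and 97.7% of cases, and 4.50% of all calls were false. The adrenergic and cAMP signalling list, with 25 measured genes each shifted by 0.5, was recovered in 10 of 10 draws. Of 250 tests of unchanged lists 0 passed. The simulated probe sets varied independently of each other. These list results therefore do not show how the list test behaves when the genes of a list are correlated. Nor do they show its power for shorter lists or for lists in which only some members change.

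RNA quality was described by the log2 ratio of 3' to 5' control probe set signals of actin, Gapdh and hexokinase, with an exact two-sided permutation test of 3 against 3 arrays, whose smallest possible p is 0.1. Alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter, a filter at the 60th percentile, eBayes without trend or with a robust prior, array weights, the replicate number as a block, leaving out each array in turn, and, for genes and lists, averaging all probe sets of a gene. Cyclic loess normalization, leaving out both arrays numbered 3, and a test of the control probe sets in the same model were added after the data were seen. Figures were drawn with matplotlib 3.10.9.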

Results

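The pineal gland makes melatonin at night, and the series compared its transcripts at the middle of the light period with those at the middle of the dark period. Pooled glands of adult rats were hybridized to 6 arrays, 3 from mid-day and 3 from mid-night. The arrays shared a trimmed mean signal of 99.99, and their highest signals ranged from 4369 to 5359. The low end differed between the groups. Median signals were 32.1, 30.7 and 29.1 on the mid-day arrays and 25.9, 25.3 and 25.3 on the mid-night arrays. Pearson correlations across kept probe sets were 0.945 to 0.968 for the 6 pairs of arrays within a group and 0.889 to 0.935 for the 9 pairs between groups. These correlations are across probe sets, which are not independent replicates. Among the hybridization controls, signals of BioB and BioC overlapped between the groups. BioB read 67.4 to 83.5 at mid-day and 63.0 to 82.7 at mid-night, and BioC 157 to 233 and 138 to 184. Signals of BioDn and CreX were lower on each mid-night array than on each mid-day array. They were 1025, 921 and 1158 for BioDn and 2442, 2579 and 3095 for CreX at mid-day, and 731, 685 and 437 for BioDn and 2393, 2088 and 647 for CreX at mid-night, in the order of the replicates.

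At mid-night, transcripts of Aanat, the enzyme that sets the pace of melatonin synthesis, stood 13.5-fold above mid-day, and those of the MAP kinase phosphatase Dusp1 stood 13.9-fold above. Aanat signal was 86.9 ± 7.79 at mid-day and 1390 ± 265 at mid-night (mean ± SD, n = 3 arrays per group here and below), with a log2 change of 3.76 ± 0.21 (SE) and a limma adjusted p of 1.8e-05. Dusp1 rose from 54.2 ± 12.1 to 949 ± 53.2. In all, 210 of 5409 probe sets were higher and 186 lower at mid-night, and 144 of the higher and 81 of the lower changed at least 2-fold. With a pseudocount of 64 these numbered 82 and 27, and with a pseudocount of 1 the falls numbered 132. On each of the 396 called probe sets the 3 arrays of a group all lay on the same side of the other 3. With 3 arrays per group the call nearly implies this, so it is not separate evidence. Over all probe sets tested, 35.6% had groups that did not overlap, against 10% by chance, and 1588 had an unadjusted p under 0.05. Both can include the low-end difference between the groups. Counted as genes, 117 were higher and 103 lower among 3246.

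The balance between rises and falls depended on the scaling. Higher probe sets made up 53.0% of the calls as deposited, 65.6% after quantile normalization, 66.1% after median centring, 71.2% after cyclic loess and 39.8% with array weights. The median log2 change of all tested probe sets was -0.13, and cyclic loess moved it by 0.12. The fall of each night-lower gene named below was larger than that shift. That comparison does not exclude background at dim probe sets, because the shift varied with signal and gene. The median change was -0.23 in the dimmest 1803 kept probe sets. It was -0.54 over 38 cytochrome P450 and olfactory receptor genes, taken as candidates for background. Of 21 night-lower genes named by the rule, 16 kept their calls under quantile normalization, median centring and cyclic loess. Bmal1, Hk1, Slc2a4, Slc6a13 and Crp lost theirs after cyclic loess. The counts also depended on single arrays. They were 113 higher and 49 lower without mid-day replicate 1, 87 and 37 without mid-day replicate 2, and 97 and 36 without mid-night replicate 2. Rises of at least 2-fold numbered 85 without mid-day replicate 2 and 95 without mid-night replicate 2, and falls of that size 42, 34 and 34 without mid-day replicate 1, mid-day replicate 2 and mid-night replicate 2 and 123 without mid-day replicate 3. Without both arrays numbered 3 the calls were 293 higher and 305 lower.

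**Figure D1:**
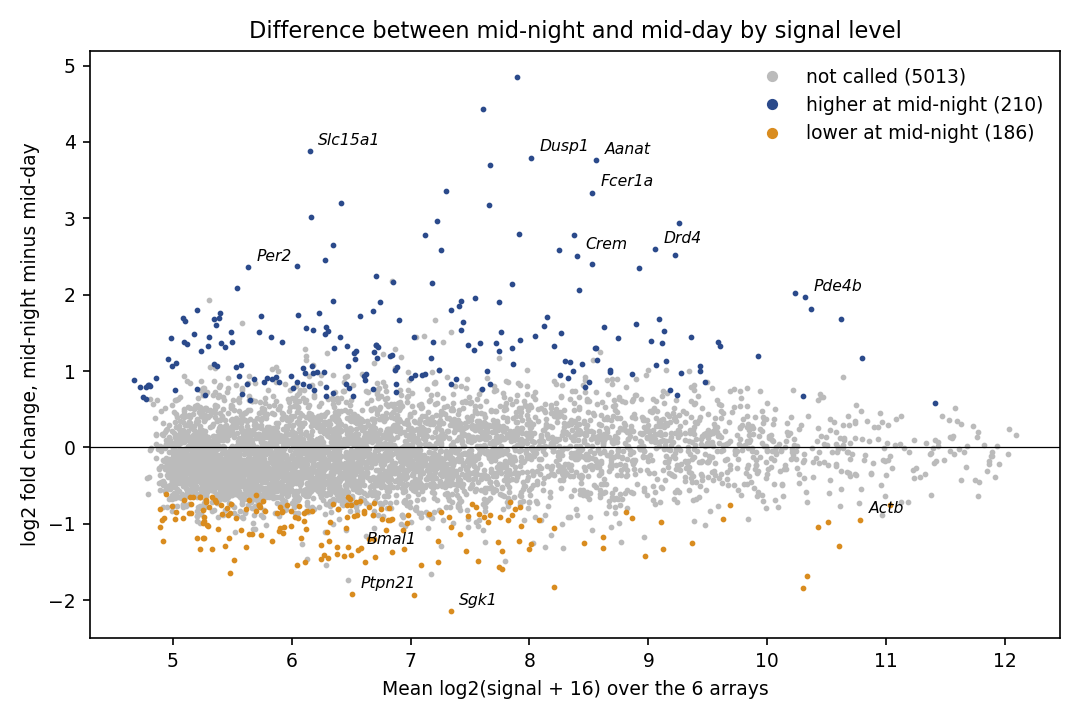
Each point is 1 of the 5409 tested probe sets, with its mean log2(signal + 16) over the 6 arrays on the horizontal axis and its log2 fold change, mid-night minus mid-day, on the vertical axis. Blue points mark the 210 probe sets called higher and orange points the 186 called lower at mid-night, and the rises extend further from 0 than the falls.

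Slc15a1, an oligopeptide transporter, had a signal of 2.69 ± 2.67 at mid-day and 275 ± 115 at mid-night. Its mid-day signal lay below the 40th percentile of all 3 arrays, so the rise was at least 7.88-fold (adjusted p = 0.00018). Fcer1a, the alpha chain of the high-affinity IgE receptor, rose 10.1-fold from 101 ± 16.6 to 1157 ± 90.5. Errfi1, an inhibitor of the EGF receptor, rose 6.91-fold, and Cd24, a surface glycoprotein, 6.89-fold. Nell2, a secreted glycoprotein, rose at least 5.87-fold from a mid-day signal below the floor. The dopamine receptor Drd4 rose 6.05-fold from 201 ± 17.5 to 1297 ± 123, the synaptotagmin Syt4 6.01-fold, and the activin-binding protein follistatin (Fst) 5.47-fold. Other probe sets of Dusp1, Fcer1a, Errfi1, Cd24, Syt4 and Fst were also called higher. The call for Fst was lost without a filter (adjusted p = 0.065), without mid-day replicate 1 (log2 change 2.43, adjusted p = 0.077) and without mid-day replicate 2 (2.34, adjusted p = 0.093). It held without mid-night replicate 1, where the change was 1.83, and without mid-night replicate 2, where it was 3.01. The calls for the other genes of this paragraph held under each alternative run.

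The falls were smaller. Sgk1, a kinase induced by glucocorticoids, fell from 336 ± 114 at mid-day to 62.7 ± 19.8 at mid-night, a log2 change of -2.14 ± 0.28 (SE; adjusted p = 0.0028), or 4.42-fold. The tyrosine phosphatase Ptpn21 was 3.80-fold lower, the Groucho-family corepressor Tle1 2.92-fold lower and Kalrn 2.76-fold lower at mid-night. The calls for Sgk1, Ptpn21, Tle1 and Kalrn held under each alternative run. Nf1, which stimulates the GTPase activity of Ras, was 2.95-fold lower, the bile acid synthesis enzyme Akr1d1 2.92-fold, the calcium channel subunit Cacnb2 2.82-fold and the membrane fusion ATPase Nsf 2.73-fold. Probe sets annotated to Rpl19l4 and Crp were 3.03-fold and 2.81-fold lower. Their names are uncertain, because probe sequences were not checked here and the identifiers of the Crp probe sets mark them as shared by a sequence family. These probe sets may measure interspersed repeats in place of the named genes, which was not tested. The other probe sets of Nsf and Cacnb2 were also called lower (-1.14 and -1.19, adjusted p = 0.018 for both), as was that of Crp (-1.51), while that of Nf1 was not called (-0.36). These last calls were less secure. Nf1 and Crp were not called without any 1 array except mid-day replicate 3 (log2 changes of -1.29 to -1.59 for Nf1 and -1.13 to -1.63 for Crp), and Rpl19l4 was not called without any 1 array except those numbered 3 (-1.34 to -1.65). Akr1d1 lost its call without mid-day replicate 1 (-1.38), mid-day replicate 2 (-1.30) or mid-night replicate 2 (-1.46), Nsf without mid-day replicate 2 (-1.34) or mid-night replicate 2 (-1.23), and Cacnb2 without mid-night replicate 2 (-1.32). Without a filter, adjusted p was 0.070 for Nf1, 0.083 for Crp, 0.066 for Rpl19l4 and 0.067 for Akr1d1, and after cyclic loess it was 0.051 for Crp.

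Of the 13 measured genes for melatonin synthesis and its cofactors, 3 rose and 0 fell at mid-night, and 3 passed when p was adjusted over the list alone. Beside Aanat, they were Mat2a, which makes the methyl donor S-adenosylmethionine, at 3.74-fold (95.8 ± 16.4 to 400 ± 45.0; adjusted p = 0.00098), and Gchfr, a regulator of GTP cyclohydrolase, whose signal was 2.84 ± 0.55 at mid-day and 18.9 ± 2.45 at mid-night, close to the floor of the arrays, at least 1.004-fold (adjusted p = 0.010). Asmt, which methylates N-acetylserotonin to melatonin, had a log2 change of 0.05 ± 0.40 (SE; adjusted p = 0.944) with signals of 752 ± 272 and 823 ± 494. Tph1, the tryptophan hydroxylase of the gland, had a log2 change of 0.01 ± 0.29 (adjusted p = 0.976), and Gch1 one of -0.16 ± 0.14 (adjusted p = 0.468). Differences in these last 3 genes were within the spread between arrays. The list's mean log2 change was 0.44 and its median 0.05. The list did not pass the list test (camera adjusted p = 0.063). It passed, with adjusted p of 0.044, 0.031 and 0.043, without mid-day replicate 3, mid-night replicate 2 and mid-night replicate 3, where its shift against other genes was 0.56, 0.59 and 0.53, and also without both arrays numbered 3 (0.047), without a filter (0.012) and over the mean of each gene's probe sets (0.034).

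Of 11 measured circadian clock genes, 4 rose and 1 fell, and 6 passed over the list alone. Per2 rose from 5.94 ± 1.65 to 97.1 ± 14.6, at least 3.24-fold (adjusted p = 8.7e-05), because its mid-day signal lay below the floor. The transcription factor Dbp rose 2.63-fold, from 308 ± 55.8 to 828 ± 49.3 (adjusted p = 0.0041), and the nuclear receptor Rorb 2.49-fold (adjusted p = 0.022). Nr1d2, chosen after its value was seen to complete the count, had a log2 change of 0.95. Bmal1, the activator of the core loop, went the other way, from 137 ± 32.6 to 47.5 ± 27.2, a log2 change of -1.35 ± 0.33 (adjusted p = 0.042), and its other probe set fell by 1.41 ± 0.17 (adjusted p = 0.0020). Nr1d1 had a log2 change of -0.30 ± 0.23 (adjusted p = 0.404), while its other probe set was called at -0.74. As a list, clock genes stood above other genes (camera adjusted p = 0.012; adjusted p = 0.377 with an estimated correlation). The list call was lost without both arrays numbered 3 (adjusted p = 0.070). The first of these Bmal1 probe sets lost its call under quantile normalization (adjusted p = 0.053), median centring (0.056), cyclic loess (0.065), no filter (0.092) and a pseudocount of 1 (0.057). It also lost it without mid-day replicate 1 (-1.25), mid-day replicate 2 (-1.26), mid-night replicate 1 (-1.42) or mid-night replicate 3 (-0.98), and Rorb lost its call without a filter (adjusted p = 0.058) and without mid-day replicate 1 (1.37) or mid-day replicate 2 (1.33).

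**Figure D2:**
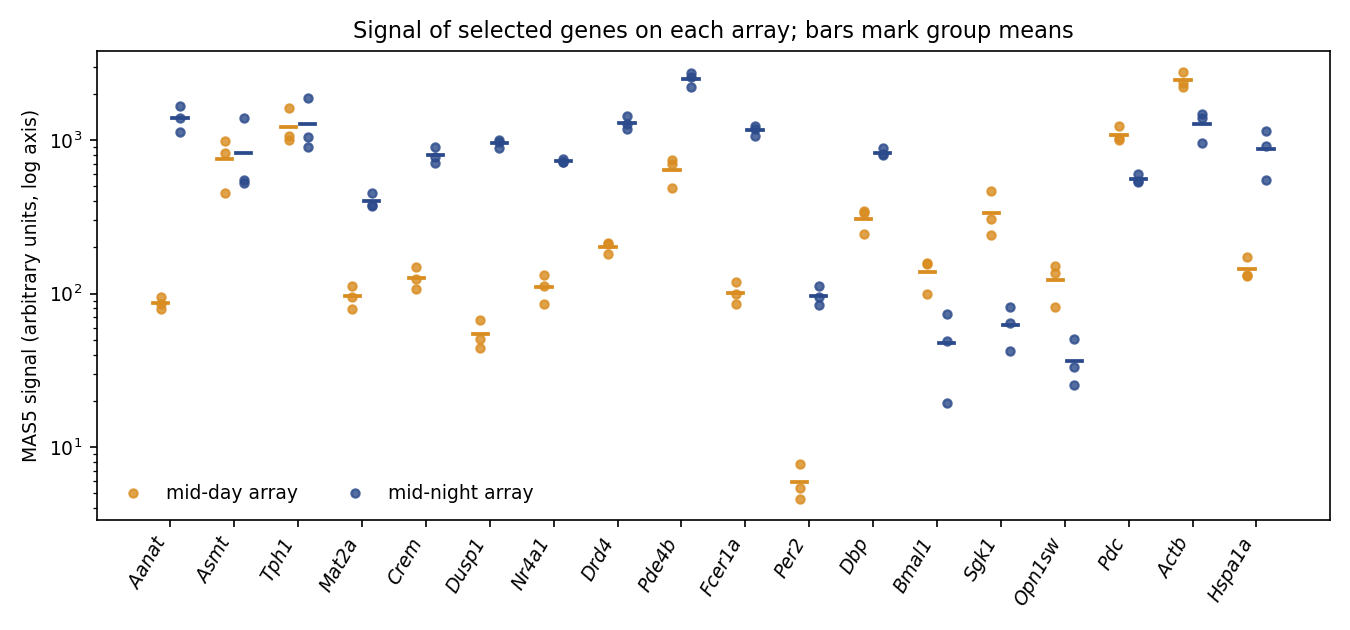
Points give the MAS5 signal of each array in arbitrary units on a log axis, orange for the 3 mid-day and blue for the 3 mid-night arrays, and short bars give group means. Among the genes plotted, Aanat, Dusp1 and Per2 separate by the widest margins, Asmt and Tph1 overlap between the groups, and Sgk1, Bmal1, Opn1sw, Pdc and Actb are lower at mid-night.

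Adrenergic and cAMP signalling genes stood above other genes as a list (camera adjusted p = 0.0021, or 0.377 with an estimated correlation). Of 25 measured members 6 rose, 0 fell and 19 did not pass, and 8 passed over the list alone. The list's mean log2 change was 0.47 and its median 0.24, and the mean was carried largely by the 6 called members. Crem, whose products include a cAMP-inducible repressor, rose 5.70-fold from 127 ± 21.9 to 796 ± 100 (adjusted p = 0.00022), and its other 2 probe sets rose by 3.20 and 4.43 on the log2 scale. The cAMP phosphodiesterase Pde4b rose 3.90-fold from 639 ± 134 to 2511 ± 267, and Pde4d at least 1.87-fold from below the floor. Drd4, described above, belongs to this list. The remaining called members, chosen after their values were seen, were protein kinase C alpha (Prkca, log2 change 1.36, adjusted p = 0.036) and the adenylyl cyclase Adcy8 (1.27, adjusted p = 0.038). Their mid-day signals were near the floor and varied between arrays, at 12.8 ± 14.95 for Prkca and 9.69 ± 10.43 for Adcy8. The beta-adrenergic receptor Adrb1 had a log2 change of 0.73 ± 0.23 (adjusted p = 0.077), and the G protein subunit Gnas one of 0.24 ± 0.12 (adjusted p = 0.201). Adrb1 passed only with array weights (0.76, adjusted p = 0.040) and without mid-night replicate 3 (0.90, adjusted p = 0.047).

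Among 25 measured immediate early genes 6 rose and 0 fell, and 10 passed over the list alone. Beside Dusp1 they were the nuclear receptor Nr4a1, at 5.98-fold (110 ± 23.0 to 729 ± 21.5; adjusted p = 0.00018), the transcription factors Cebpb, at 3.30-fold, and Egr1, at 2.73-fold (395 ± 141 to 1074 ± 139), and, chosen after their values were seen, Junb (log2 change 1.34) and Id1 (1.31). Of the other probe sets of Egr1, 2 were called higher and 1 was not called (0.31, adjusted p = 0.230). Fosl2 had a log2 change of 0.65 ± 0.28 (adjusted p = 0.159), and Fos, also chosen after its value was seen, one of -0.57. Btg1 and Id3 had log2 changes of 0.03 and -0.53 (adjusted p = 0.931 and 0.294), while the other probe set of Id3 was called lower (-0.91, adjusted p = 0.028). The list mean was 0.47 and its median 0.03, so the shift rested on a minority of its members (camera adjusted p = 0.012; adjusted p = 0.493 with an estimated correlation). Without mid-night replicate 1 the shift against other genes was 0.50 and not called (adjusted p = 0.081). Egr1 lost its call without mid-day replicate 2 (1.34, adjusted p = 0.062) or mid-night replicate 2 (1.36, adjusted p = 0.056).

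Protein folding and heat shock genes stood above other genes as a list (camera adjusted p = 0.0021, or 0.493 with an estimated correlation). The list did not pass in fry (adjusted p = 0.073). Of 21 measured members 5 rose, 0 fell and 16 did not pass, and 6 passed over the list alone. The list's mean log2 change was 0.43 and its median 0.18, and the mean was carried largely by the 5 called members. The inducible heat shock protein Hspa1a rose 5.30-fold from 145 ± 23.8 to 867 ± 297 (adjusted p = 0.0015), the endoplasmic reticulum chaperone Hspa5 2.88-fold (318 ± 55.2 to 937 ± 40.04), and Ddit3, a transcription factor of the unfolded protein response, 3.12-fold. The co-chaperone Dnajb1 rose 2.03-fold (adjusted p = 0.045), and Dnaja1, chosen after its value was seen, was called at a log2 change of 0.99. Hsp90ab1 had a log2 change of 0.10 ± 0.14 (adjusted p = 0.668) and Hspb1 one of -0.54 ± 0.23 (adjusted p = 0.159), while another probe set of Hsp90ab1 was called higher and 2 others of Hspb1 lower. Averaged over its probe sets, Hspb1 was called at -0.91 (adjusted p = 0.0082). Dnajb1 was not called under quantile normalization (adjusted p = 0.060), cyclic loess (0.057) or no filter (0.080), as the mean of its probe sets (0.68, adjusted p = 0.134), or without mid-day replicate 1 (0.94), mid-day replicate 2 (0.97), mid-night replicate 1 (0.77) or mid-night replicate 2 (1.09).

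Of 16 measured phototransduction and photoreceptor-type genes, which the pineal gland shares with the retina, 0 rose and 2 fell, and 7 passed over the list alone. The short-wavelength opsin Opn1sw fell from 123 ± 36.0 to 36.4 ± 12.7, a log2 change of -1.40 ± 0.26 (adjusted p = 0.015), and phosducin (Pdc), which binds G protein beta and gamma subunits, from 1084 ± 131 to 557 ± 38.7, a change of -0.94 ± 0.17 (adjusted p = 0.016). Arrestin (Sag) had a log2 change of 0.68 ± 0.22 (adjusted p = 0.090), and its other probe set was called higher at 0.998. Averaged over both, Sag was called at 0.84 (adjusted p = 0.018). Unc119 and Tulp1 had log2 changes of -0.20 and -0.38 (adjusted p = 0.368 and 0.247). The list's mean was -0.38 and its median -0.29 (camera adjusted p = 0.208), and it passed only without mid-night replicate 3 (shift -0.41, adjusted p = 0.043). Opn1sw and Pdc lost their calls without mid-day replicate 2 (-1.25 and -0.84) or mid-night replicate 2 (-1.24 and -0.90), and Opn1sw also without mid-day replicate 1 (-1.31). The low-end signal was higher on the mid-day arrays, with 10th percentiles of 2.18 to 2.72 against 1.498 to 2.06.

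No gene of the 7 measured pineal and retinal transcription factors passed over all probe sets in limma, and 2 passed over the list alone (camera adjusted p = 0.991). Isl2 had a log2 change of -0.68 (adjusted p = 0.061), which passed after quantile normalization (0.044), with array weights (0.034) and in the fit with 1 averaged value per gene (0.047), and Neurod1 one of -0.20 (adjusted p = 0.666). Of 12 measured genes of thyroid hormone and retinoid signalling, 1 rose, 0 fell and 3 passed over the list alone (camera adjusted p = 0.991). The gene that rose was Dio2, the deiodinase that activates thyroxine, from 3.45 ± 0.30 to 45.4 ± 8.03, at least 1.76-fold given its mid-day signal below the floor (adjusted p = 0.00063). Ttr and the retinoid receptor Rxrg had log2 changes of 0.14 and -0.47 (adjusted p = 0.558 and 0.175).

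Among 22 genes of metal handling and redox, 2 rose and 0 fell, with 2 passing over the list alone (camera adjusted p = 0.558). They were the copper pump Atp7b, which rose at least 2.76-fold from 6.93 ± 4.63 to 83.7 ± 35.5, and the zinc exporter Slc30a1, at 3.37-fold (26.4 ± 14.2 to 128 ± 49.4; adjusted p = 0.012). Of 24 ion channels and transporters 3 rose, 2 fell and 9 passed over the list alone (camera adjusted p = 0.214). Beside Slc15a1 and Cacnb2, the sodium-potassium-chloride cotransporter Slc12a2 rose 3.01-fold (147 ± 35.2 to 470 ± 50.7) and the large neutral amino acid transporter Slc7a5 2.66-fold (136 ± 37.6 to 386 ± 89.4), while the potassium channel Kcnh2, chosen after its value was seen, had a log2 change of -0.73. Among 22 genes of secretory vesicles and the synapse, Syt4 rose and the vesicle protein Sv2b fell 2.37-fold (1022 ± 229 to 425 ± 117; adjusted p = 0.024), and 7 passed over the list alone (camera adjusted p = 0.421). Slc30a1 lost its call without mid-day replicate 1 (1.55) or mid-day replicate 2 (1.71), and Slc7a5 without mid-day replicate 1 (1.33), mid-day replicate 2 (1.30) or mid-night replicate 2 (1.39). Sv2b lost it without mid-day replicate 1 (-1.21), mid-day replicate 3 (-1.10) or mid-night replicate 2 (-1.02), without a filter (adjusted p = 0.058) and as the mean of its probe sets (adjusted p = 0.196).

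Of 20 genes of glucose and energy metabolism 0 rose and 3 fell, and 4 passed over the list alone (camera adjusted p = 0.5). Cpt1a, which controls the entry of fatty acids into mitochondria, fell from 398 ± 120 to 146 ± 27.4, a log2 change of -1.33 ± 0.25 (adjusted p = 0.017). Hexokinase Hk1 fell by 0.97 on the log2 scale (adjusted p = 0.042), and the glucose transporter Slc2a4, near the floor at mid-night with a signal of 11.8 ± 3.64, by 0.96 (adjusted p = 0.030). Cpt1a lost its call without mid-day replicate 1 (-1.10) or mid-day replicate 2 (-1.41). Hk1 lost it under median centring (adjusted p = 0.059), cyclic loess (0.052) and no filter (0.074), and without mid-day replicate 1 (-0.96), mid-day replicate 2 (-0.89), mid-night replicate 1 (-1.002) or mid-night replicate 2 (-0.77). Slc2a4 lost it under quantile normalization (adjusted p = 0.053), cyclic loess (0.062), no filter (0.074) and with both arrays numbered 3 left out (0.076), and without mid-day replicate 1 (-0.79), mid-day replicate 3 (-0.95), mid-night replicate 1 (-0.98), mid-night replicate 2 (-1.05) or mid-night replicate 3 (-0.86).

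In limma, 0 of the 21 measured respiratory chain genes, 0 of the 28 cytosolic ribosomal protein genes and 0 of the 17 cholesterol and fatty acid synthesis genes passed, over all probe sets or over the list alone. Their camera adjusted p were 0.214, 0.284 and 0.991. The respiratory chain list had a mean log2 change of -0.28 and an adjusted p of 0.048 in fry, which does not compare it with other genes, and it passed in camera only after cyclic loess (adjusted p = 0.042). Among 13 cell cycle genes Ccne1 fell by 0.83 on the log2 scale (77.4 ± 6.44 to 36.6 ± 6.84; adjusted p = 0.023), with 3 passing over the list alone (camera adjusted p = 0.991). Pcna and Ccnd2 had log2 changes of 0.61 and 1.15 and were not called (adjusted p = 0.075 and 0.063). Ccne1 lost its call without a filter (adjusted p = 0.059), with both arrays numbered 3 left out (0.059), and without mid-day replicate 1 (-0.81), mid-day replicate 2 (-0.89) or mid-night replicate 2 (-0.78).

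Of 10 genes often used as references 2 fell, 0 rose and 2 passed over the list alone (camera adjusted p = 0.991). Actb fell from 2438 ± 292 to 1275 ± 280, a log2 change of -0.94 ± 0.20 (adjusted p = 0.024), and Tubb5 from 890 ± 243 to 352 ± 147, a change of -1.34 ± 0.31 (adjusted p = 0.036). Both remained negative and called after quantile normalization, median centring and cyclic loess. Pgk1 and Rplp0 had log2 changes of -0.06 and -0.23 (adjusted p = 0.851 and 0.370). Actb was not called without a filter (adjusted p = 0.068) or without mid-day replicate 1 (-0.97), mid-day replicate 2 (-1.01), mid-day replicate 3 (-0.85) or mid-night replicate 2 (-0.75). Tubb5 was not called without a filter (adjusted p = 0.077) or without mid-day replicate 1 (-1.31), mid-day replicate 2 (-1.15), mid-night replicate 1 (-1.10) or mid-night replicate 2 (-1.27). The log2 ratio of 3' to 5' actin control signal was 0.32 ± 0.30 at mid-day and 0.92 ± 0.46 at mid-night (exact permutation p = 0.2, smallest possible 0.1). The ratio was 1.28 ± 0.18 and 1.02 ± 0.44 for Gapdh (exact p = 0.5) and 1.38 ± 0.88 and 1.797 ± 0.31 for hexokinase (exact p = 0.6).

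**Figure D3:**
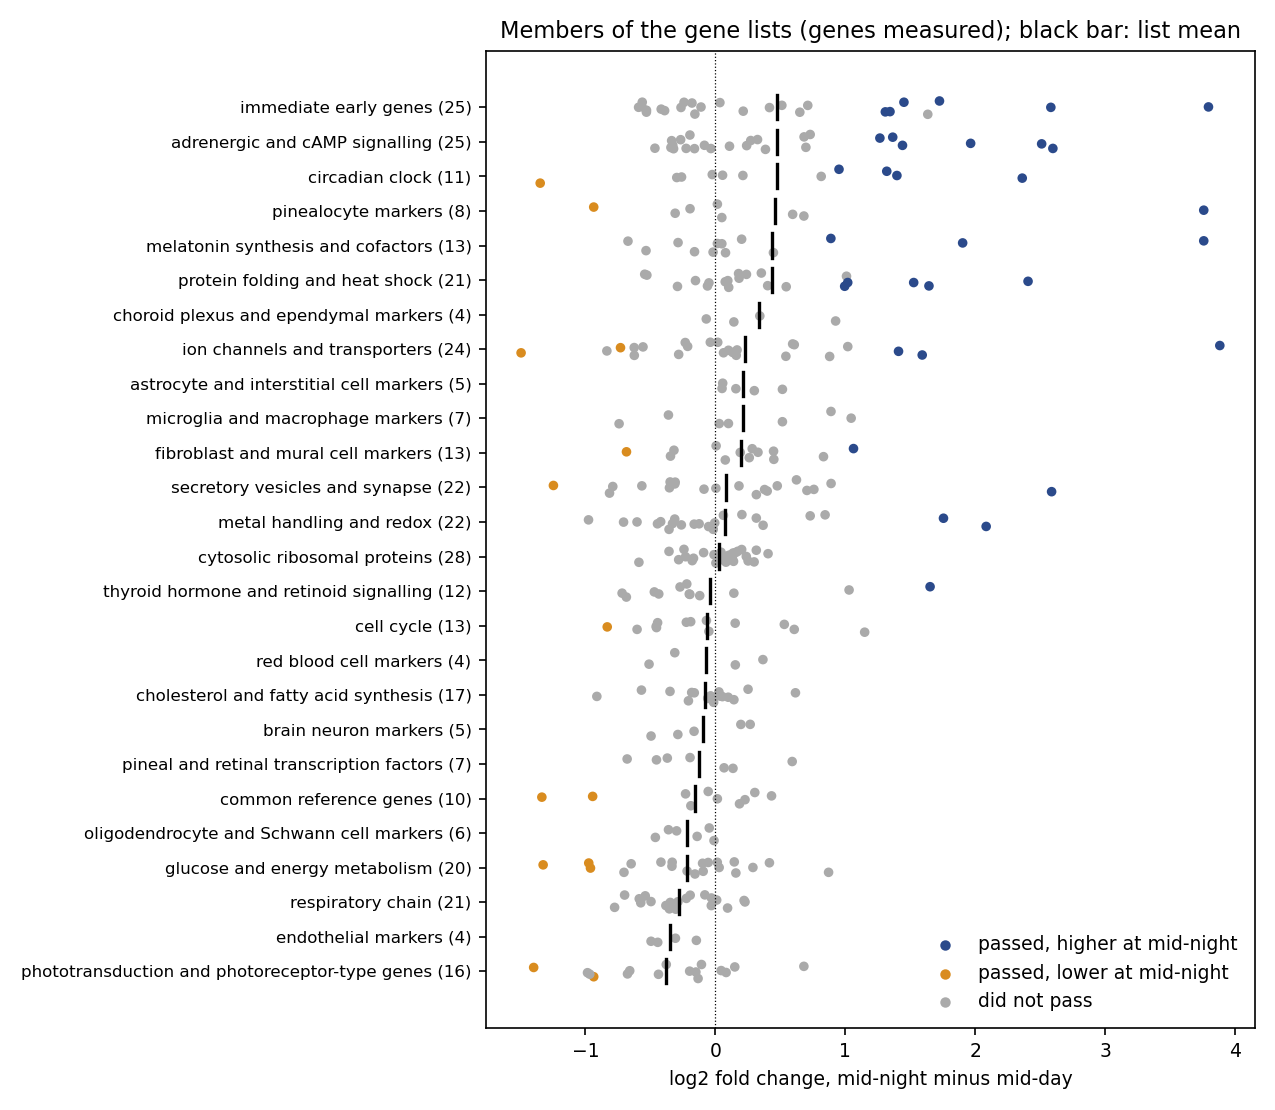
Each point is the log2 fold change, mid-night minus mid-day, of 1 measured gene of a list, for the 26 lists with at least 4 measured genes (their number in brackets). Blue and orange points passed the test and were higher or lower at mid-night, grey points did not pass, and black bars give list means, which are 0.47 for each of the adrenergic, clock and immediate early lists.

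Markers of the cell types a dissected gland could hold gave 1 rise and 1 fall outside the pinealocyte list. Both were among the 13 fibroblast and mural cell markers (2 over the list alone; camera adjusted p = 0.214), a list that passed only without mid-day replicate 1 (shift 0.45, adjusted p = 0.018). The matrix proteoglycan Dcn rose from 472 ± 110 to 1003 ± 234 (adjusted p = 0.032), and the transporter Slc6a13 was 27.5 ± 1.81 at mid-day and 11.1 ± 2.77, below the floor, at mid-night, at least 1.41-fold lower (adjusted p = 0.035). Among 8 pinealocyte markers Aanat rose and Pdc fell, and 3 passed over the list alone (camera adjusted p = 0.284). The mean log2 change of these 8 was 0.46 and the median 0.03, so the mean rested mainly on Aanat (3.76). In limma 0 genes passed, over all probe sets or the list alone, among 5 astrocyte, 7 microglia, 4 endothelial, 6 oligodendrocyte and Schwann cell, 4 red blood cell, 4 choroid plexus and ependymal and 5 brain neuron markers. Their camera adjusted p were, in that order, 0.254, 0.389, 0.5, 0.5, 0.991, 0.284 and 0.991. Another probe set of the astrocyte marker Glul was called higher (0.78, adjusted p = 0.047), while the brightest of that gene was not (0.52, adjusted p = 0.120). The microglia marker Cd74 was called higher only without mid-day replicate 3 (1.28, adjusted p = 0.045) and without both arrays numbered 3 (1.37, adjusted p = 0.048). The brain neuron marker Calb2 was called lower only with array weights (-0.56, adjusted p = 0.044). For skeletal muscle only Myh1 was measured (log2 change -0.72, adjusted p = 0.214). Among individual markers, Ptgds varied from array to array, with 493 ± 610 at mid-day and 603 ± 376 at mid-night. Dcn was not called without a filter (adjusted p = 0.067), as the mean of its probe sets (0.061), or without mid-day replicate 1 (0.92), mid-day replicate 2 (1.03), mid-night replicate 1 (1.07) or mid-night replicate 2 (0.89). Slc6a13 was not called under quantile normalization (adjusted p = 0.069), median centring (0.054), cyclic loess (0.097) or no filter (0.060), or without mid-day replicate 1 (-0.71), mid-day replicate 2 (-0.69), mid-day replicate 3 (-0.65), mid-night replicate 1 (-0.67) or mid-night replicate 2 (-0.62).

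Of the 26 lists tested, 6 had an unadjusted camera p under 0.05 and 4 passed after adjustment, all upward, while 0 passed with an estimated correlation. Other splits of the 6 arrays, 3 against 3, gave up to 6 called lists, so the number of called lists does not set the real grouping apart. In fry, adjusted p was 0.0055 for the clock list, 0.024 for the adrenergic list and 0.036 for the immediate early and melatonin lists. It was 0.048 for the glucose, respiratory chain and pinealocyte lists, whose mean log2 changes were -0.22, -0.28 and 0.46. The mean and median had opposite signs for the metal and redox list (0.07 and -0.09) and for the secretory list (0.08 and -0.04). For the reference and the cholesterol lists, mean and median were below 0 while camera's direction was up.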

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

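The control probe sets for rat transcripts lie outside the comparison, and their test in the same limma model was chosen after the data were seen. Of 7 tested, 4 differed between the groups. The actin controls were lower at mid-night by -0.80 (3' end, adjusted p = 0.025), -1.39 (5' end, adjusted p = 0.029) and -1.21 (middle, adjusted p = 0.046) on the log2 scale, and the hexokinase 3' control by -1.17 (adjusted p = 0.013). Signals of the actin 3' control were 2486 ± 401 at mid-day and 1413 ± 129 at mid-night (SD, n = 3). The Gapdh controls did not pass, at 0.26, 0.51 and 0.51 (adjusted p = 0.427, 0.367 and 0.365). The actin controls measure the same transcript as Actb, which was also called lower, so they are a second reading of the same RNA on the same arrays and not independent samples.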

How the results depend on the processing

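Cyclic loess and leaving out both arrays numbered 3 were added after the data were seen. Of the 52 named genes that were called, 24 of 31 night-higher and 4 of 21 night-lower genes passed under every alternative run, and 0 changed sign. The main counts were 210 higher, 186 lower, and 144 and 81 at least 2-fold. Counts past 1.5 times apart were, with a pseudocount of 1, 132 falls of at least 2-fold; with a pseudocount of 64, 82 rises and 27 falls of at least 2-fold; after quantile normalization 118 lower; without a filter, where more dim probe sets share the adjustment, 122 higher, 79 lower and 40 falls of at least 2-fold; with array weights 358 higher, 541 lower and 132 falls of at least 2-fold; after cyclic loess 97 lower and 52 falls of at least 2-fold; without both arrays numbered 3, 305 lower, 229 rises and 181 falls of at least 2-fold. Leaving out each array in turn gave 87 to 242 higher, 36 to 245 lower, and 85 to 193 rises and 34 to 123 falls of at least 2-fold. Fewer arrays leave less power, but the cause of the rises in count without arrays numbered 3 was not tested. Robust and untrended priors and the 60th percentile filter kept all 4 counts within 1.5 times.

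An estimated correlation leaves the shift against other genes as it is by construction. All 4 called lists lost their calls with it, the clock list although its estimate of -0.0551 lay below the preset 0.01, so the correlation alone does not account for the losses. The fewer degrees of freedom that camera uses with an estimated correlation raise its p-values as well. The shifts were 0.547 (clock), 0.551 (adrenergic and cAMP), 0.552 (immediate early) and 0.513 (folding). Over all alternatives the adjusted p of the clock list ran from 0.00243 to 0.377 and that of the immediate early list from 0.00195 to 0.493. The clock shift was 0.545 without both arrays numbered 3 (adjusted p = 0.0699), and the immediate early shift ran from 0.501 to 0.646 with single arrays left out (lowest without mid-night replicate 1). The cause of these changes with arrays left out was not tested. The uncalled melatonin list passed under 6 alternatives, and the phototransduction, respiratory chain and fibroblast lists under 1 each. The RNA ratios moved within their spread in all 18 fits.

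The replicate numbers 1 to 3 are shared by the groups, and the labels do not say whether a number marks a shared day or batch. Deviations from the group means correlated at 0.0763, -0.0129 and 0.106, and 4 of 6 arrays lay closest to their own number. These values neither show nor exclude a pairing. With the replicate block 203 were higher and 192 lower, of which 180 and 147 were also called without it, and among named genes Dnajb1, Hk1 and Slc6a13 were not called (adjusted p = 0.0578, 0.0598 and 0.0518). Ccnd2, which was not called without the block, was called higher with it (1.148, adjusted p = 0.0217). Signal over background was not used here, so calls among dim probe sets are the least secure.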

Other observations

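Beyond the genes the rule names, the next called genes by size of change were examined after their values were seen, and alternatives were not run for them. At mid-night Fdx1, the electron donor of mitochondrial cytochrome P450 enzymes, rose 4.07-fold from 584 ± 77.2 to 2448 ± 501 (SD, n = 3 arrays; limma adjusted p = 0.00063). The insulin-like growth factor receptor Igf1r rose 3.59-fold, the salt-inducible kinase Sik2 3.06-fold, the receptor kinase Tyro3 2.89-fold and the membrane fission GTPase Dnm2 3.28-fold. Latexin (Lxn), an inhibitor of carboxypeptidases, rose 4.19-fold, and Pmepa1, a negative regulator of TGF-beta signalling, 3.20-fold to 2831 ± 552. Gdf15, a secreted stress-responsive factor, rose 2.89-fold and the keratin Krt19 2.99-fold.

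Among the next falls were Gucy1a1, a subunit of the nitric oxide-sensitive guanylyl cyclase, from 354 ± 45.8 to 141 ± 1.56 (2.34-fold, adjusted p = 0.0062), Pla2g4a, the cytosolic phospholipase that releases arachidonic acid, at 2.66-fold, and Egf, at 2.47-fold from 61.6 ± 11.4 to 15.2 ± 1.88. Hook1, a microtubule-linked adaptor, fell 2.68-fold from 817 ± 157, and Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, 2.498-fold. Probe sets whose identifiers mark them as shared by a sequence family numbered 123, of which 11 were lower and 1 higher at mid-night. Among all 5409 tested, 186 were lower and 210 higher. Probe sets of a family can read related sequences and are not independent of each other, so no p-value is given. This count was made after the data were seen.

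Of the tests that follow, those of low-end signal, of genes foreign to the gland, of mixed RNA and of scaling for the largest changes were chosen after the result was seen. The tests of the scaling of mid-day replicate 3, the pseudocount and other splits of the arrays were set before their results were known.

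With the kept probe sets divided by signal into 3 sets of 1803, 63 fell and 51 rose in the dimmest, 72 and 71 in the middle and 51 and 88 in the brightest, with median log2 changes of -0.23, -0.14 and -0.000916, so falls weighed more among dim than bright probe sets although most were not in the dimmest set. Cyclic loess, which removes a trend with signal, left 31.75% of the 63 falls called (20), while all 51 rises remained called. The median of the 63 went from -0.86 to -0.67 with SEs of 0.18 and 0.17, and over the 43 that ended from -0.78 to -0.60, each of them smaller, while 6 of the 43 had a p that would still have been called at the earlier bound of 0.00366. Cytochrome P450 families 1 to 4 and olfactory receptors, 38 measured genes taken as candidates for background signal, had a median log2 change of -0.54 (9 fell, 0 rose), below 10000 random lists matched on signal (-0.33 to -0.05), and -0.37 after cyclic loess. The loess result is consistent with higher low-end signal on the mid-day arrays as a source of part of the dim falls, while the fall of the P450 and olfactory genes beyond matched lists is more than a shift by signal level gives and may reflect a background that differs between probe sets, and a real fall of dim transcripts at mid-night, which loess would also remove, stays open.

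Mid-day replicate 3 lay toward the mid-night arrays. Its position was taken on a scale from 0 at the other mid-day arrays to 1 at the mid-night arrays. The median was 0.42 over 245 night-lower and 0.29 over 242 night-higher probe sets called without it. Mid-night replicates 1 and 3 also lay off their own group, at 0.32 and 0.34 for night-lower probe sets. Mid-day replicates 1 and 2 and mid-night replicate 2 lay at 0.04, 0.11 and -0.01. Choosing probe sets on the other arrays by itself places the left-out array toward the other group, which was not corrected. The sets also differed, with 37 and 36 night-lower probe sets for mid-day replicate 2 and mid-night replicate 2. Without such a choice, mid-day replicate 3 correlated with the mid-night arrays at 0.920 to 0.935, and mid-day replicates 1 and 2 at 0.889 to 0.914. Mid-night RNA mixed into the pool would add 1 share of the mid-night signal at all transcripts. That share was 0.00774 in the median and 0.0664 at most over the 13 night-higher probe sets of at least 8-fold. It was 0.181 in the median over all 242 and 0.524 over the night-lower ones, which were chosen in the same way. Insofar as the larger shares are not due to that choice, the low share at the 13 argues against mixed RNA as the whole cause. Signal-dependent scaling of that array is argued against too, since 104.1% of its position remained after cyclic loess. A position due to the choice of probe sets could remain as well. A difference between pools of animals or in their handling stays open and was not tested.

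Rises outnumbered falls among changes of at least 2-fold, at 64% of 225 probe sets. The test of scaling between arrays leaves its part open. Under quantile normalization, median centring and cyclic loess the lowest share was 69.64%. The median log2 change was -0.13 as deposited, and these scalings raised it by 0.079, 0.086 and 0.117, in that order. Raising the median adds rises and removes falls, so this test could hardly have lowered the share. The test of the pseudocount leaves its part open too. With 1 in place of 16 the share was 56.29%, between the bounds set beforehand for either answer, and with 64 it was 75.23%. A difference between mid-day and mid-night in the gland, with transcripts that are low by day and induced at night, stays a hypothesis.

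The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 396 called probe sets and 225 of at least 2-fold, each the largest count in 1 of the 10 splits, and the highest other was 0 for both. It gave 4 called lists, reached or passed by 3 of the 10 splits, and the highest other was 6. Those 6 were found with mid-day replicates 1 and 2 and mid-night replicate 3 as a group, and with mid-day replicate 1 and mid-night replicates 1 and 2 as a group.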
